A study of Caenorhabditis elegans with 16 samples.

How the data were processed

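Total RNA was sequenced from mixed-stage embryos of Caenorhabditis elegans. Per the labels' protocols, synchronized larvae of each genotype were grown in parallel to gravid adults, embryos were harvested by bleaching and frozen, RNA was extracted with Trizol and treated with DNase, and 4 independent biological replicates per genotype were made into stranded total RNA libraries with a TruSeq Gold kit. The genotypes were WT (N2), edc-3(ok1427), edc-4(qe49) and the double mutant, and each library was placed in its group by the genotype in its labels. The replicate numbers 2 to 5 are those of the labels.

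The deposited table holds raw counts, whole numbers of reads per gene and library, which the authors made with Trimmomatic, STAR and HTSeq on the WBcel235 genome, per the submitters' processing notes. Those notes also name edgeR and limma. Tool versions, the annotation release and the strand setting of HTSeq are not given in the sources used here. Reads of genes that overlap on opposite strands can therefore not be assumed to have been told apart. Of 48 genes called in any comparison, 8 overlapped another annotated gene on the same strand, 16 overlapped one on the other strand and 26 overlapped none. The library type keeps ribosomal RNA that the depletion did not remove, and this stayed in the counts. The table has 46726 genes, of which 12753 have 0 counts in every library, and each entry names a gene. Current symbols were taken by identifier for 43623 genes, which changed 1688 symbols (edc-4 is listed as Y44E3A.6 in the table), and positions for 46364 genes from the Ensembl release 115 annotation of WBcel235. Library totals ranged from 34.1 to 52.9 M counts. No 2 libraries held identical values, and replicate pairs differed by a chi-square of 12.6 to 233 per degree of freedom, well above sampling noise.

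Counts were analysed in R 4.3.3. Genes were filtered with filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total 15), which left 16880, and libraries were scaled with TMM factors. All 16 libraries entered 1 quasi-likelihood fit (glmQLFit, glmQLFTest) with a mean per genotype, so that the groups shared an estimate of the spread; the common biological coefficient of variation was 0.193. Contrasts were each mutant against WT, the double mutant against each single mutant, and the interaction of both alleles. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. Levels are TMM-scaled CPM, and the standard error of a log2 fold change is its size divided by the square root of its F statistic. Log2 CPM used a prior count of 2.

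The comparisons, tests, gene lists, alternatives and rule for named genes were fixed before the data were examined. Named genes were edc-3 and edc-4, then up to 10 rises and 10 falls of largest log2 fold change per mutant against WT, among genes past the threshold with a mean of at least 5 CPM over the 8 libraries and no overlap between mutant and WT libraries. Each gene list added up to 2 risers and 2 fallers past the threshold. For the double mutant against each single mutant and for the interaction the same rule took up to 5 rises and 5 falls. Genes named outside this rule are marked in the text as chosen after their values were seen. Names of list members that did not pass over all genes were likewise chosen after their values were seen.

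A total of 30 gene lists were fixed, by gene name or name prefix, and 29 with at least 5 measured members were tested with camera of limma 3.58.1 on voom values, with the preset correlation of 0.01. Camera with an estimated correlation and fry were run beside it. The lists covered processing body and decapping factors, mRNA deadenylation and decay, germ granules, small RNA pathways, maternal mRNAs, early zygotic genes, tissue markers (muscle, epidermis and cuticle, collagens, hedgehog-related genes, neurons, neuropeptides and insulins, intestine, vitellogenins, sperm), heat shock and other chaperones, the pals family, immune effectors, detoxification enzymes, histones, ribosomal proteins, the respiratory chain, the mitochondrial genome, the proteasome, the cell cycle, nuclear hormone receptors, chemoreceptors, F-box and MATH-BTB families and heterochronic genes. Levels of the targeted transcripts were tested with exact two-sided permutation tests of log2 CPM. Calls per chromosome, and within 2 Mb of each targeted gene, were tested with two-sided Fisher's exact tests over the tested genes with a position.

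The pipeline was tested on simulated data for the double mutant against WT, with 16664 genes after the filter. It recovered 20.4% of genes changed 1.5-fold, 72% of genes changed 2-fold, 92% changed 4-fold and 100% changed 8-fold, and 5 of 147 calls (3.4%) were false. Changes of 1.5-fold were thus mostly missed at this depth and number of libraries. A list with all members shifted by 0.4 on the log2 scale was found (adjusted p = 9.24e-19, and 3.87e-06 with an estimated correlation), with 0 other lists called. In this simulation genes varied independently, which real lists do not.

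Alternatives were other scalings (RLE, upper quartile, totals alone), other filters, DESeq2 1.42.0, limma-voom, a replicate block, a fit with only the groups compared, each library left out in turn, a stage covariate (each library's mean z-scored level of the muscle and the epidermis and cuticle lists), an adjusted p under 0.01, and removal of ribosomal and mitochondrial genes. A fit without the 4 libraries numbered 4, the effect of each allele averaged over both backgrounds, chromosome tests without the targeted genes and overlaps with separate WT libraries were added after the data were examined. The medians of all genes under the 4 scalings lay between log2 -0.08 and 0.03, and no called list changed direction between scalings.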

Results

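RNA was sequenced from mixed-stage embryos of Caenorhabditis elegans in 4 genotypes. These were the wild-type strain N2 (WT), an edc-3(ok1427) mutant, an edc-4(qe49) mutant and the double mutant carrying both alleles. EDC-3 and EDC-4 are enhancers of mRNA decapping, the removal of the 5' cap that commits an mRNA to decay, and both are components of the cytoplasmic RNA granules called processing bodies. Each genotype was represented by 4 independent biological replicates, numbered 2 to 5 by the submitters, for 16 libraries in all. The libraries held 34.1 to 52.9 M counts assigned to genes, with a median of 44.0 M. Mean depth was 44.7 ± 3.398 M in WT, 40.6 ± 6.26 M in edc-3, 46.0 ± 7.43 M in edc-4 and 40.8 ± 3.56 M in the double mutant (SD, n = 4 each). Nuclear ribosomal RNA took 15.4 ± 2.43% of the counts in WT, 13.5 ± 1.73% in edc-3, 13.99 ± 0.97% in edc-4 and 17.6 ± 2.67% in the double mutant (SD, n = 4 each). After low counts were filtered, 16880 genes were tested.

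The levels of the targeted transcripts were examined first. The edc-4 transcript (WBGene00021551, chromosome I, 3340212 to 3349914 in WBcel235) stood at 168 ± 20.5 CPM in WT and 176 ± 22.8 CPM in edc-3 (SD, n = 4 each). It fell to 31.9 ± 2.62 CPM in edc-4, which was 19.0% of WT, and to 26.1 ± 4.37 CPM in the double mutant, 15.5% of WT. Every library with the edc-4 allele lay below every library without it, and each comparison with WT gave the smallest p that an exact two-sided permutation test of 4 against 4 libraries allows (p = 0.0286). The edc-3 transcript (WBGene00011036, chromosome I, 8602125 to 8605162) was at 62.4 ± 5.55 CPM in edc-3 and 72.8 ± 7.49 CPM in the double mutant, against 85.4 ± 11.5 CPM in WT and 92.5 ± 16.3 CPM in edc-4 (SD, n = 4 each). These levels were 73.1% of WT in edc-3 (exact p = 0.0286) and 85.3% in the double mutant (exact p = 0.143). Across all genes neither edc-3 difference passed, with adjusted p = 0.676 in edc-3 and 0.471 in the double mutant by the edgeR quasi-likelihood test. With any of the 4 edc-3 libraries left out, the exact test in edc-3 did not pass (exact p = 0.0571 each time), where 3 against 4 libraries allow a p of 0.0286. The counts are per whole gene, so a deletion inside edc-3 that leaves the rest of the transcript in place is not visible in them, and the edc-3 genotype was not checked by this level.

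**Figure D1:**
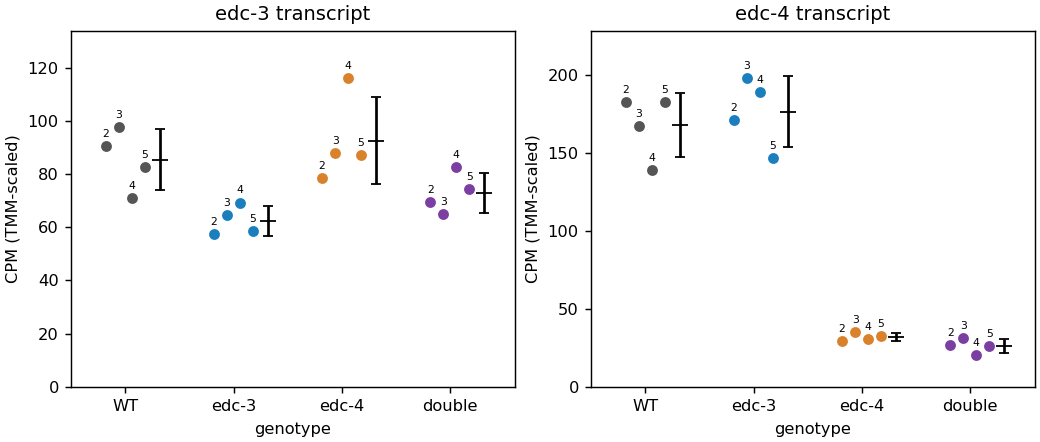
TMM-scaled CPM (vertical axes starting at 0) of the edc-3 and edc-4 transcripts in the 4 libraries of each genotype, with points numbered by replicate and bars for the mean ± SD (n = 4). The edc-4 transcript averaged 31.9 CPM in edc-4 and 26.1 CPM in the double mutant against 168 CPM in WT, while the edc-3 transcript averaged 62.4 CPM in edc-3 against 85.4 CPM in WT.

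The embryo libraries differed along 1 main axis within every genotype. The first principal component held 36.05% of the variance, and the libraries numbered 4 lay at its ends, with scores of -52.3 in WT, 21.2 in edc-3, 53.8 in edc-4 and 53.8 in the double mutant. Along this axis, genes first transcribed in the early embryo and genes of differentiated muscle moved in opposite directions. The early zygotic list averaged 2.49 log2 CPM in WT replicate 4, 3.87 in edc-4 replicate 4 and 3.96 in double replicate 4. The muscle list averaged 7.26, 6.46 and 6.35 log2 CPM in the same 3 libraries. For the gene lists called against WT, results without the libraries numbered 4 are given beside the main values.

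**Figure D2:**
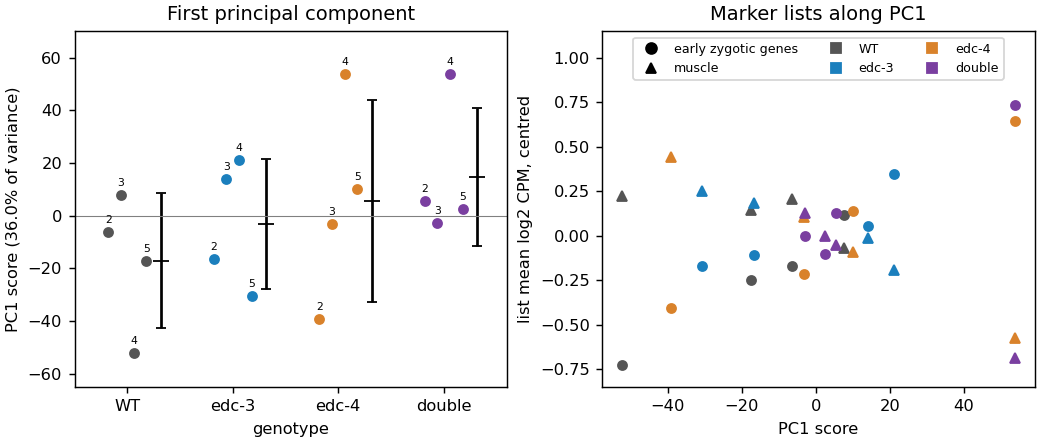
Left, score of each library on the first principal component (36.05% of variance) by genotype, with points numbered by replicate and bars for the mean ± SD (n = 4). Right, mean log2 CPM of the early zygotic list (circles) and the muscle list (triangles), centred on the mean of the 16 libraries, against that score, where the libraries numbered 4 of edc-4 and the double mutant sit at 53.8 with high early zygotic and low muscle levels.

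Which transcripts differed with the edc-3 allele was asked by comparing the edc-3 mutant with WT. Among the genes higher in edc-3 embryos were chs-1, egg-1 and egg-2. The chitin synthase gene chs-1 (chromosome I, 7554855 to 7559916), whose product makes the chitin of the eggshell, rose 4.91-fold, from 16.8 ± 7.22 to 82.4 ± 20.7 CPM (log2 2.29, SE 0.26, adjusted p = 0.000114). The genes egg-1 (chromosome III, 5728180 to 5730159) and egg-2 (chromosome III, 7058527 to 7060583) encode related oocyte surface proteins needed for fertilization. They rose 3.56-fold and 3.13-fold, to 21.8 ± 7.66 and 25.23 ± 6.47 CPM, with adjusted p = 0.040 and 0.0123. The small nucleolar RNA gene F59C6.15 (chromosome I, 10516978 to 10517150) rose 62.2-fold, from 6.77 ± 1.01 to 422 ± 21.9 CPM (adjusted p = 6.13e-11). In the other direction, lmd-1 (chromosome I, 8609921 to 8611066), which encodes a LysM domain protein, fell from 19.7 ± 1.55 to 0.442 ± 0.204 CPM (log2 -5.52, SE 0.26, adjusted p = 3.81e-10; all values SD, n = 4). The lmd-1 gene starts 4.76 kb beyond the end of edc-3. Between them lie F43G9.13 and idha-1, with log2 differences of 0.10 and -0.04 that did not pass. Some of these genes overlap an annotated neighbour, chs-1 with T25G3.3 on the same strand. On the other strand, egg-1 overlaps B0244.9 and lmd-1 overlaps F43G9.4, so reads there may not be told apart.

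Further changes in edc-3 clustered on chromosome II. The gene rer-1, for a membrane protein that returns cargo to the endoplasmic reticulum, fell from 149 ± 14.3 to 53.9 ± 2.73 CPM (log2 -1.47, SE 0.11, adjusted p = 3.88e-07). Its neighbours pho-13, an acid phosphatase gene, appg-2 and F46C5.9 fell by 1.48, 1.49 and 1.05 on the log2 scale, and T25D10.1 and T25D10.4 fell by 1.09 and 0.99. On chromosome I the translation initiation factor gene eif-3.I rose 1.86-fold, the DEAD-box helicase gene ddx-10 1.87-fold and Y23H5B.5 1.75-fold. The mitochondrial ABC transporter gene abtm-1 rose 1.37-fold and the pseudogene C18H2.2 1.66-fold. The cytochrome P450 gene cyp-31A2 rose 2.46-fold (adjusted p = 0.0443), but the near-identical cyp-31A3 had log2 0.88 and did not pass, and reads could be split between these copies. Among low-count genes, chosen for naming after their values were seen, F46C5.2 was at 4.76 ± 1.35 CPM in edc-3 against 0.0507 ± 0.0586 CPM in WT, where the 4 libraries held 4, 5, 0 and 0 counts. C55C3.3 was at 2.21 ± 0.331 against 0.286 ± 0.0647 CPM, and the pseudogene Y51A2D.23 at 1.27 ± 0.415 against 0.107 ± 0.0441 CPM (SD, n = 4 each).

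In total, 24 genes differed between edc-3 and WT, 16 higher and 8 lower, by the edgeR quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, and 448 had an unadjusted p under 0.05. Without TMM scaling the split was 17 higher and 5 lower. The count was 14 with the edc-3 and WT libraries alone in the fit, 39 by DESeq2 (28 higher and 11 lower), 45 with a stage covariate (32 and 13), 40 without a filter on low counts, 15 without edc-3 replicate 2, 14 without edc-3 replicate 3 and 22 without the libraries numbered 4. Of 17 named genes, 8 kept their call when any 1 library was left out, among them chs-1, F59C6.15, lmd-1 and rer-1, while egg-1 lost it without WT replicate 5 or edc-3 replicate 2, 3 or 4 (log2 1.55 to 2.12 over all settings) and egg-2 without WT replicate 5 or edc-3 replicate 3 (log2 1.38 to 1.81). The other 7 that lost it were abtm-1 and appg-2 in 7 of the 8 such fits, C18H2.2 in 6, cyp-31A2 in 5, ddx-10 and T25D10.1 in 3 and eif-3.I in 2.

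Gene lists fixed in advance gave the following for edc-3. Of 42 measured maternal mRNAs of the oocyte and early embryo, 36 had positive fold changes, with a median of log2 0.23. Among them chs-1, egg-1 and egg-2 passed over all genes, and 7 passed when adjusted over the list alone. The additional 4 were rme-2, the yolk receptor of oocytes (log2 1.72, SE 0.40), cbd-1, a chitin-binding eggshell gene (log2 1.43, SE 0.37), the RNA-binding protein gene lin-41 (log2 1.33, SE 0.38) and the nanos gene nos-1 (log2 0.70, SE 0.24). By limma camera the maternal list was called upward (adjusted p = 1.84e-15), which was lost with an estimated correlation (adjusted p = 0.878 with an estimated correlation). Cytosolic heat shock genes, which encode chaperones, had positive values in 17 of 18 members and a median of log2 0.34, with no member passing (adjusted p = 7.77e-06 by camera and 0.878 with an estimated correlation). Early zygotic genes had positive values in 35 of 38 members (median log2 0.27), histones in 54 of 59 (log2 0.16), cell cycle genes in 39 of 39 (log2 0.12), small RNA pathway genes in 33 of 39 (log2 0.11), germ granule genes in 19 of 26 (log2 0.12), proteasome genes in 31 of 33 (log2 0.11) and processing body genes in 15 of 17 (log2 0.05). F-box and MATH-BTB genes were called upward as well (median log2 0.09), and neuronal genes (median log2 -0.09), nuclear hormone receptors (-0.05) and cytosolic ribosomal proteins (-0.04) downward. No member of these 11 lists passed over all genes. In all, 13 of 29 lists were called by camera, and each had adjusted p = 0.878 with an estimated correlation. With the stage covariate 10 of the 13 calls held, and those of processing body genes, neurons and ribosomal proteins ended. Without the libraries numbered 4 the heat shock list kept its call (median log2 0.63), 1 of the 13, the maternal median was -0.03, and the germ granule, proteasome and cell cycle lists were called downward instead. The number of lists called was 5 without WT replicate 4, 6 without edc-3 replicate 4 and 20 without edc-3 replicate 5.

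The effect of the edc-4 allele was asked in the same way against WT. The targeted transcript fell by 2.395 on the log2 scale (SE 0.14, adjusted p = 1.78e-08). Chromosome II again held most of the falls. There rer-1 fell from 149 ± 14.3 to 56.4 ± 6.31 CPM (log2 -1.40, SE 0.11, adjusted p = 9.17e-07), and pho-13, appg-2, F46C5.9, T25D10.1 and T25D10.4 fell by 1.71, 1.51, 0.98, 1.154 and 0.64 on the log2 scale. The pseudogenes Y46G5A.6 and Y46G5A.43, which adjoin each other on chromosome II, fell by 1.56 and 1.58. They went from 14.19 ± 5.445 to 4.80 ± 0.446 CPM and from 14.65 ± 5.77 to 4.905 ± 0.502 CPM. WT replicate 2 held only 6.62 and 6.42 CPM of them, well below the other WT libraries. Levels of Y46G5A.6 were also low in edc-3 (7.18 to 9.04 CPM) and the double mutant (5.80 to 7.27 CPM), without a call there, so the fall was not particular to edc-4. Among rises, ddx-10 increased 2.08-fold and Y23H5B.5 1.69-fold, and eif-3.I went from 200 ± 48.9 to 400 ± 33.1 CPM (adjusted p = 0.00485). The ephrin gene efn-4, which acts in cell movement during embryonic enclosure, rose from 68.4 ± 9.04 to 96.8 ± 6.23 CPM (log2 0.50, SE 0.10, adjusted p = 0.0467). T26C12.3 rose from 45.5 ± 3.81 to 71.2 ± 6.12 CPM (adjusted p = 0.0057), and F59C6.15 from 6.77 ± 1.01 to 17.2 ± 7.30 CPM (adjusted p = 0.0057). From the pals family, of which some members are induced by intracellular infection, pals-16 rose from 1.59 ± 0.287 to 3.80 ± 0.673 CPM (adjusted p = 0.00421; all values SD, n = 4). The eggshell gene chs-1 was at 19.0 ± 3.74 CPM in edc-4 against 16.8 ± 7.22 CPM in WT, which did not pass.

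In total, 24 genes differed between edc-4 and WT, 12 higher and 12 lower, by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, and 840 had an unadjusted p under 0.05. The count was 7 with these 2 groups alone in the fit, 42 by DESeq2 (24 higher and 18 lower), 88 with a stage covariate (56 and 32), 15 without edc-4 replicate 5 and 21 without the libraries numbered 4. Of 16 named genes, 12 kept their call when any 1 library was left out, while efn-4 and appg-2 each lost it in 6 of these fits, T25D10.1 without edc-4 replicate 3 or 5 and T25D10.4 without edc-4 replicate 5.

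Among gene lists in edc-4, proteasome genes had positive fold changes in 32 of 33 members, with a median of log2 0.22 (camera adjusted p = 2.86e-08, and 0.846 with an estimated correlation). Without the libraries numbered 4 that median was -0.025. Early zygotic genes were positive in 37 of 38 members (median log2 0.38), maternal mRNAs in 40 of 42 (log2 0.21), cell cycle genes in 38 of 39 (log2 0.20) and nuclear-encoded respiratory chain genes in 41 of 42 (log2 0.10). Histones, germ granule, processing body, deadenylation and decay, and small RNA genes were also called upward, with medians of log2 0.18, 0.17, 0.12, 0.11 and 0.11. Neuronal genes were negative in 29 of 33 members (median log2 -0.13) and muscle genes in 26 of 32 (log2 -0.12). Nuclear hormone receptors (log2 -0.10), chemoreceptors (-0.08), detoxification enzymes (-0.07) and cytosolic ribosomal proteins (-0.05) were called downward. No member of these lists passed over all genes, and none passed when adjusted over the list alone. Camera called 16 of 29 lists, and each had adjusted p = 0.846 with an estimated correlation. With the stage covariate 13 of the 16 calls held, with the early zygotic median at log2 0.16, and those of small RNA, muscle and ribosomal protein genes ended. The muscle list is itself part of that covariate, so the end of its call follows from the adjustment. Without the libraries numbered 4, calls in the same direction remained for 2 of the 16, the respiratory chain (median log2 0.10) and detoxification (log2 -0.04) lists, while germ granule, small RNA and cell cycle lists were called downward and cytosolic ribosomal proteins upward (median log2 0.14, adjusted p = 7.58e-08) instead. Without WT replicate 4, 4 lists were called.

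The double mutant was compared with WT to see both alleles together. The genes chs-1, egg-1 and egg-2 were again higher, with chs-1 up 5.19-fold to 87.2 ± 2.89 CPM (log2 2.38, SE 0.26, adjusted p = 9.43e-05). The fertilization genes egg-1 and egg-2 rose 4.09-fold and 3.66-fold, to 24.98 ± 3.69 and 29.5 ± 5.11 CPM, with adjusted p = 0.0126 and 0.00319. The Argonaute gene ppw-2, of the small RNA pathway, rose 1.74-fold from 14.3 ± 1.68 CPM in WT (SD, n = 4, adjusted p = 0.0456), and pals-26 from 1.62 ± 0.232 to 3.62 ± 0.862 CPM (adjusted p = 0.0264). F58D5.5 rose 2.25-fold, from 88.5 ± 9.58 to 199 ± 48.7 CPM, and the small nucleolar RNA F58D5.11, which lies inside it on the same strand, rose 2.397-fold, so their reads could be shared. Y65A5A.1 rose 1.66-fold, ddx-10 2.02-fold, eif-3.I 1.90-fold and Y23H5B.5 1.77-fold. Among falls, lmd-1 was at 0.697 ± 0.209 CPM (log2 -4.81, SE 0.25, adjusted p = 1.58e-09) and edc-4 itself changed by log2 -2.69 (SE 0.14, adjusted p = 1.58e-09). The proton and myo-inositol transporter gene hmit-1.1 fell from 8.74 ± 1.82 to 3.13 ± 0.844 CPM (adjusted p = 0.0294), and the scramblase family gene scrm-4 from 7.35 ± 3.66 to 2.90 ± 0.610 CPM (adjusted p = 0.0375; all values SD, n = 4). The chromosome II genes rer-1, pho-13, appg-2, F46C5.9, T25D10.1 and T25D10.4 fell by 1.29, 1.93, 1.81, 0.87, 1.02 and 0.54 on the log2 scale.

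In total, 35 genes differed between the double mutant and WT, 20 higher and 15 lower, by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, and 1933 had an unadjusted p under 0.05. The count was 113 by DESeq2 (81 higher and 32 lower), 199 with a stage covariate (149 and 50), 65 without a filter on low counts, 22 without WT replicate 4, 21 without WT replicate 5, 17 without double replicate 2 and 31 without the libraries numbered 4. Of 21 named genes, 12 kept their call when any 1 library was left out, among them chs-1, egg-2, lmd-1 and F58D5.5, whereas egg-1 lost it without WT replicate 5 or double replicate 2 and ppw-2, F58D5.11 and scrm-4 each lost it in 7 of the 8 such fits. T25D10.4 lost it in 6 of them, T25D10.1, hmit-1.1 and pals-26 in 5 and F46C5.9 in 4.

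**Figure D3:**
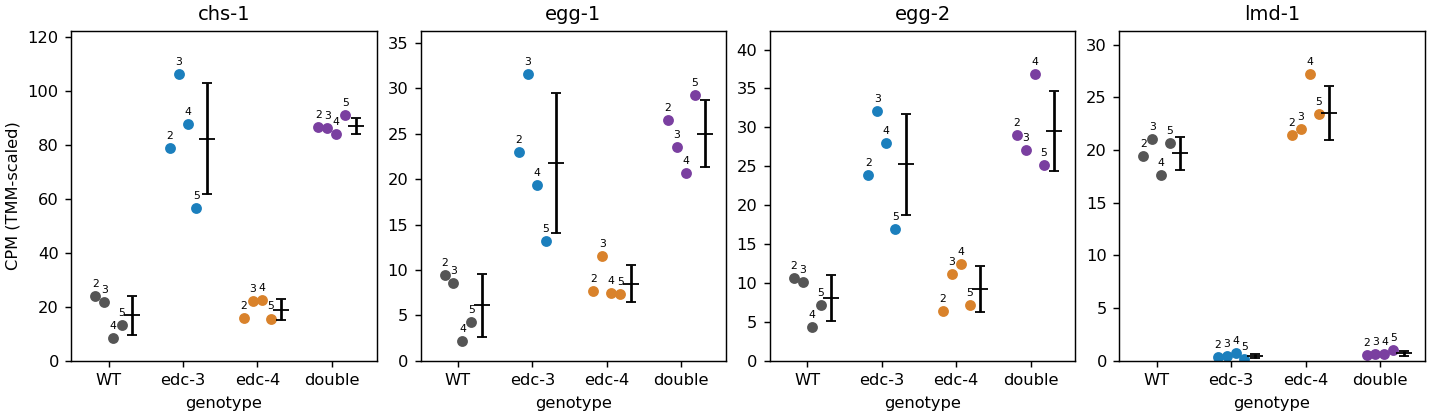
TMM-scaled CPM (vertical axes starting at 0) of chs-1, egg-1, egg-2 and lmd-1 in the 4 libraries of each genotype, with points numbered by replicate and bars for the mean ± SD (n = 4). The chs-1 transcript averaged 82.4 CPM in edc-3 and 87.2 CPM in the double mutant against 16.8 CPM in WT and 19.0 CPM in edc-4, and lmd-1 averaged 0.442 and 0.697 CPM in the 2 genotypes with the edc-3 allele.

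In the double mutant camera called lists in both directions with its preset correlation, and none with an estimated correlation. Maternal mRNAs were positive in 39 of 42 members, with a median of log2 0.37 (camera adjusted p = 6.49e-14, and 0.601 with an estimated correlation), 3 members passing over all genes and 7 when adjusted over the list alone. Early zygotic genes were positive in 38 of 38 members (median log2 0.45, camera adjusted p = 8.36e-10, and 0.601 with an estimated correlation). Proteasome (log2 0.28), cell cycle (0.23), small RNA (0.22), germ granule (0.19), heat shock (0.37), processing body (0.15), histone (0.13) and deadenylation and decay (0.09) lists were called upward. In the processing body list, the DEAD-box helicase gene cgh-1 had log2 0.99 (SE 0.24), which passed when adjusted over the list alone (adjusted p = 0.0102) and not over all genes (0.154). Cytosolic ribosomal protein genes were negative in 78 of 81 members (median log2 -0.20, camera adjusted p = 2.08e-10, and 0.601 with an estimated correlation). Negative medians were also called for the mitochondrial genome (log2 -0.45), intestine (-0.37), muscle (-0.32), neurons (-0.27), hedgehog-related genes (-0.25), collagens (-0.20), immune effectors (-0.20) and nuclear hormone receptors (-0.13). With the stage covariate 13 of the 19 calls held, with smaller medians for early zygotic genes (log2 0.21) and muscle (-0.145), and those of intestine (-0.185), hedgehog-related genes (-0.09), collagens (-0.08), immune effectors (-0.105), histones (-0.02) and deadenylation and decay (0.06) ended. As part of the covariate, the muscle list has a smaller median by construction. The germ granule and small RNA lists share 1 member that passed over all genes, ppw-2. No other list named here beyond the maternal one had such a member. Camera called 19 of 29 lists, with adjusted p = 0.601 with an estimated correlation for each except histones (0.640). Without the libraries numbered 4, 10 lists were called, and 5 of the 19 calls remained in the same direction. These were the maternal (median log2 0.17, adjusted p = 7.03e-10), heat shock (0.58), early zygotic (0.12), processing body (0.05) and cytosolic ribosomal protein (-0.07) lists, while histones were called downward instead.

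**Figure D4:**
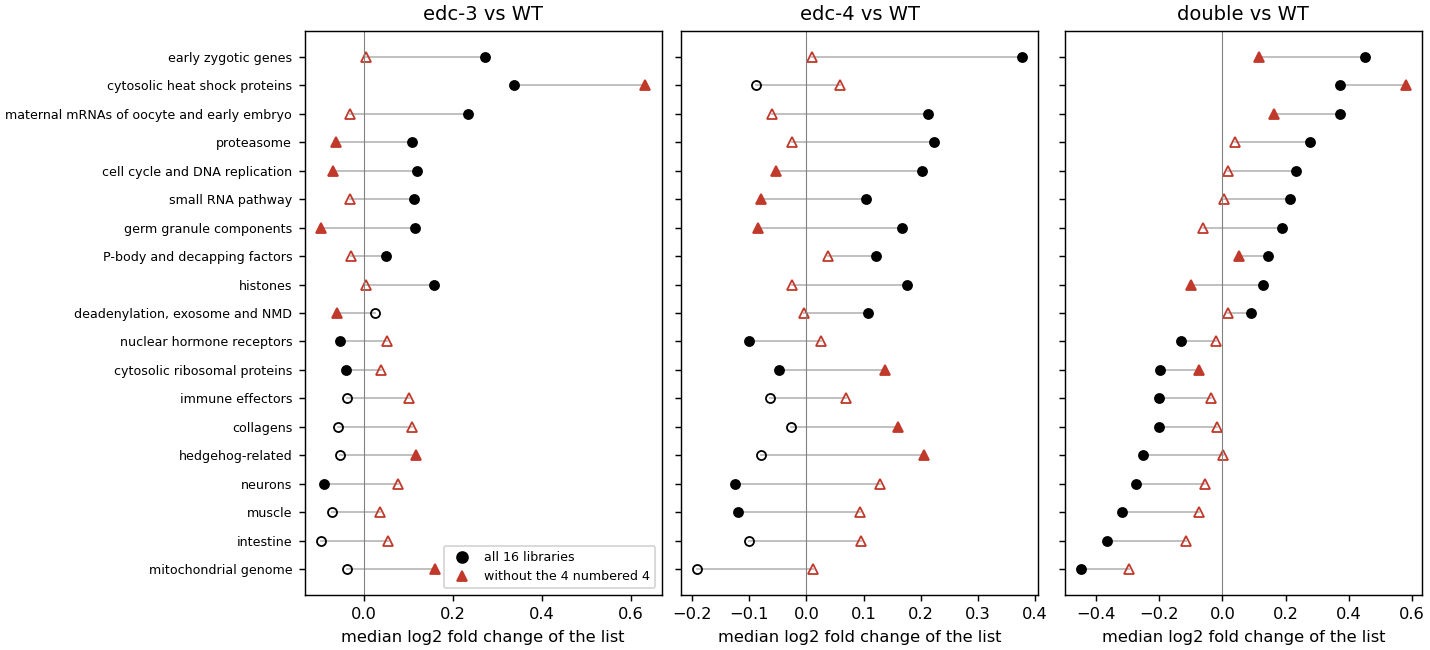
Median log2 fold change against WT (horizontal axes, scaled separately for each mutant) of the gene lists called in the double mutant, with all 16 libraries (circles) and without the 4 libraries numbered 4 (triangles), where filled symbols passed camera at an adjusted p under 0.05 with the preset correlation. Lists called only in a single mutant are not drawn. The maternal list had medians of 0.23, 0.21 and 0.37 with all libraries, and 0.17 in the double mutant without those numbered 4.

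With all 16 libraries, the remaining lists were called in none of the mutants. They covered epidermis and cuticle genes, with medians of log2 -0.06, -0.04 and -0.06 in edc-3, edc-4 and the double mutant, neuropeptides and insulins (-0.04, -0.02 and -0.12), sperm genes (-0.02, 0.03 and 0.00), chaperones of the endoplasmic reticulum and mitochondria (0.08, 0.06 and 0.01), heterochronic genes (-0.09, -0.01 and 0.00) and the pals family (-0.07, -0.18 and 0.07). The epidermis and cuticle list differed along the main library axis, averaging 5.55 log2 CPM in WT replicate 4, 4.69 in edc-4 replicate 4 and 4.86 in double replicate 4. Its small medians could therefore depend on those libraries. The insulin gene ins-4 passed in the double mutant when adjusted over the list alone (adjusted p = 0.0386), at 0.274 ± 0.0996 against 0.0609 ± 0.0193 CPM (SD, n = 4 each), and not over all genes. Adjusted over their lists alone, the heterochronic genes lin-41 in edc-3 (adjusted p = 0.0205) and lin-41 and lin-29 in the double mutant (adjusted p = 0.0202 and 0.0391) were higher, as were pals-16 in edc-4 and pals-26 and pals-16 in the double mutant (adjusted p = 4.72e-05, 0.000789 and 0.0367). By fry's test for change in either direction the pals family passed in edc-4 (adjusted p = 0.0157) and in the double mutant (adjusted p = 0.000366). Of the 6 vitellogenin genes, which are made in the adult intestine, 1 was measured, so that list was not tested.

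The edc-4 allele in the presence of the edc-3 allele was examined in the double mutant against edc-3. F59C6.15 was at 6.46 ± 0.811 CPM in the double mutant and 422 ± 21.9 CPM in edc-3 (log2 -6.03, SE 0.25, adjusted p = 5.5e-11), so the level in the double mutant lay near the 6.77 ± 1.01 CPM of WT. The edc-4 transcript differed by log2 -2.76 (SE 0.14, adjusted p = 1.07e-09). The remaining calls, named after their values were seen, were C55C3.3 (log2 -3.39), the pseudogene Y51A2D.23 (-3.52), Y102A5C.36 (-2.23) and T07G12.5 (-1.27), all below 3 CPM in both genotypes. In total 6 genes were lower and 0 higher in the double mutant by the edgeR quasi-likelihood test, with 845 at an unadjusted p under 0.05. The direction depended on the method, with 25 genes by DESeq2, 14 higher and 11 lower, and 40 with a stage covariate, 28 higher and 12 lower.

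The edc-3 allele in the presence of the edc-4 allele was examined in the double mutant against edc-4. The chitin synthase gene chs-1 was 4.59-fold higher in the double mutant, at 87.2 ± 2.89 against 19.0 ± 3.74 CPM (log2 2.198, SE 0.26, adjusted p = 0.000801). The fertilization gene egg-2 was 3.19-fold higher, at 29.5 ± 5.11 against 9.26 ± 2.97 CPM (adjusted p = 0.0266). Levels of pals-26, named after its values were seen, were 3.62 ± 0.862 and 1.42 ± 0.224 CPM (adjusted p = 0.0266). In the other direction lmd-1 fell from 23.5 ± 2.59 to 0.697 ± 0.209 CPM (log2 -5.06, SE 0.25, adjusted p = 1.44e-09) and F59C6.15 from 17.2 ± 7.30 to 6.46 ± 0.811 CPM (adjusted p = 0.0155; all values SD, n = 4). These were all 5 calls of the edgeR quasi-likelihood test, 3 higher and 2 lower, with 474 genes at an unadjusted p under 0.05. The count was 2 without double replicate 2, 3 or 5, 3 without edc-4 replicate 2 or 5, 12 by DESeq2, 12 without a filter on low counts and 9 with a stage covariate, and egg-2 lost its call in 7 of the 8 fits that left out 1 library and F59C6.15 in 3.

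Whether the effects of both alleles added on the log2 scale was tested with the interaction term, which is 0 for additive effects. F59C6.15 had the most negative term, log2 -7.37 (SE 0.32, adjusted p = 1.22e-10), since it was 422 CPM in edc-3 and 6.46 CPM in the double mutant. For rer-1 the term was 1.59 (SE 0.15, adjusted p = 2.35e-05), with log2 -1.47, -1.40 and -1.29 in edc-3, edc-4 and the double mutant against WT, and for T25D10.4 it was 1.09 (SE 0.14, adjusted p = 0.00145), with -0.99, -0.64 and -0.54. The other 3 calls, named after their values were seen, were the low-count genes F46C5.2, nas-25 and F46C5.4, where WT libraries held between 0 and 5 counts. In total 6 genes passed by the edgeR quasi-likelihood test, 2 positive and 4 negative, with 274 at an unadjusted p under 0.05. With upper quartile scaling the split was 3 positive and 3 negative, and the count was 17 by DESeq2, 15 with a stage covariate and 10 without a filter on low counts.

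Changes shared by the mutants lay close together in the genome. All 3 mutants differed from WT in 14 genes in the same direction, 7 higher and 7 lower. Of these, eif-3.I, ddx-10 and Y23H5B.5 were higher and lay at 2.49 to 2.51 Mb on chromosome I. T25D10.1, T25D10.4 and the noncoding RNA gene K03H9.10 were lower and lay at 6.40 to 6.41 Mb on chromosome II. The other 8 lay at 8.80 to 8.84 Mb on chromosome II, where appg-2, pho-13, F46C5.9 and rer-1 were lower and the astacin protease gene nas-25, F46C5.2, F46C5.4 and F46C5.7 were higher. F46C5.7 had 0 counts in all 4 WT libraries. Of the calls against WT, 15 of 24 in edc-3, 15 of 24 in edc-4 and 17 of 35 in the double mutant lay within 100 kb of these 3 clusters, which hold 140 tested genes. In each mutant 14 of these are the genes that define the clusters. Several of these genes overlap a neighbour, appg-2 with pho-13 and nas-25 with F46C5.2 on opposite strands and F46C5.4 with F46C5.7 on the same strand, so reads may not be told apart there.

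**Figure D5:**
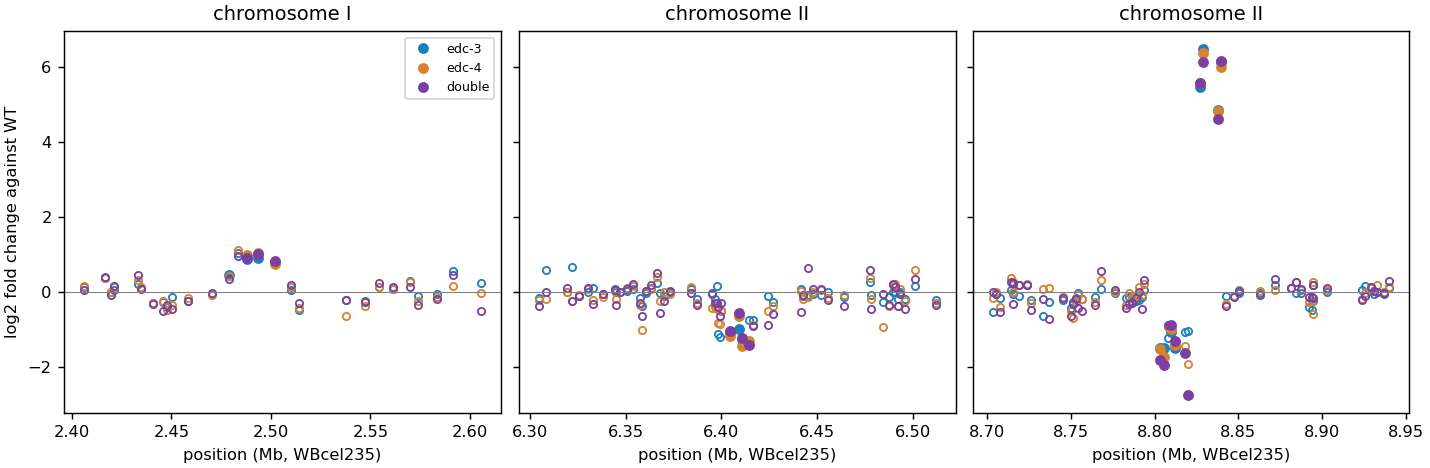
Log2 fold change against WT (vertical axis) of every tested gene within 100 kb of the 3 clusters of genes called in all 3 mutants, by position in WBcel235 (horizontal axes, Mb), coloured by mutant, with filled points for genes called at an adjusted p under 0.05. The clusters at 2.49 to 2.51 Mb of chromosome I and at 6.40 to 6.41 and 8.80 to 8.84 Mb of chromosome II hold 14 genes called in all 3 mutants, 7 higher and 7 lower.

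Calls shared by edc-3 and edc-4 numbered 8 among genes higher and 7 among genes lower. Of these 15, all but F59C6.15 belonged to the 14 genes above. The edc-3 calls shared 10 higher and 8 lower genes with the double mutant, and the edc-4 calls shared 8 higher and 9 lower. Each of these comparisons uses the same WT libraries, which by itself makes calls overlap. When edc-3 and edc-4 were each compared with their own 2 WT libraries, an alternative added after the data were examined, 2 higher and 1 to 3 lower genes were shared over the 6 divisions, where independent lists would share at most 0.0114 and 0.00237, and all of them belonged to the 14. Over 16880 genes the fold changes of edc-3 and edc-4 correlated with Pearson r = 0.561 and Spearman rho = 0.579, across genes, which are not independent replicates. Both use the same WT libraries, and simulated groups without any effect gave a mean r of 0.501 (0.486 to 0.516 in 20 simulations). The covariance was 0.0395 against 0.0326 in the simulations, a difference of 0.00694. Genes varied independently in the simulations, unlike in these libraries, so neither excess can be read as beyond chance. With the WT libraries divided so that each mutant had 2 of its own, r ranged from -0.14 to 0.22 over the 6 divisions.

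By chromosome, genes called against WT were more frequent on chromosome II in all 3 mutants. There were 11 of 24 calls in edc-3 (4.17 expected, adjusted p = 0.0106), 14 of 24 in edc-4 (4.17 expected, adjusted p = 0.000181) and 14 of 35 in the double mutant (6.08 expected, adjusted p = 0.0106) by two-sided Fisher's exact tests, adjusted over 24 tests. On chromosome I the double mutant had 11 calls (5.38 expected, adjusted p = 0.0477), and on chromosome V edc-4 had 0 (4.75 expected, adjusted p = 0.0405). Within 2 Mb of edc-4 lay 4, 4 and 5 calls in edc-3, edc-4 and the double mutant (adjusted p = 0.0405 each), among them eif-3.I, ddx-10 and Y23H5B.5, but the counts in edc-4 and the double mutant include the targeted gene edc-4 itself. With both targeted genes left out, an alternative added after the data were examined, 4, 3 and 4 calls lay there (adjusted p = 0.0696, 0.118 and 0.105), chromosome I in the double mutant had 10 calls (adjusted p = 0.105), chromosome V in edc-4 had adjusted p = 0.0696, and only chromosome II still passed (adjusted p = 0.00928, 9.02e-05 and 0.00928). Within 2 Mb of edc-3 lay 3, 2 and 2 calls, which did not pass. Neighbouring genes are not independent, and the clusters above supply most of the chromosome II calls.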

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

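The tests of stage, of neighbouring positions, of adding effects, of linkage to edc-3 and of the libraries numbered 4 were chosen only after the result was seen, while the tests of other groupings of the libraries, of adult tissue and of ribosomal RNA were chosen before.

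The 14 genes that differed from WT in all 3 mutants lay in 3 short stretches of chromosomes I and II, where all 14 had another of the set within 100 kb, against at most 6 in 10000 random draws of tested genes. A different mix of embryo stages, as muscle and cuticle genes track it, is argued against. With that stage covariate 14 of 14 remained called in all 3 comparisons. Effects of EDC-3 and EDC-4 that add up are argued against too, because the interaction, signed by the direction of change, had a median of log2 -1.244 (quartiles -4.18 and -1.11) where 0 is needed, and the double mutant changed by a median of 1.26 against 1.39 in the single mutants. Sequence background that the mutant strains share and the WT strain used here lacks stays open as a hypothesis. Sites that differ between laboratory stocks would be such a background, and the clustering (14 of 14) goes with it. An effect of losing either factor that does not add up in the double mutant would give the same interaction. It was not tested and stays open too.

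Levels of chs-1, egg-1 and egg-2 were higher in both genotypes with the edc-3 allele. A different mix of stages, as muscle and cuticle genes track it, is argued against as the whole cause. With that stage covariate 6 of 6 calls held (log2 1.61 to 2.32), and all 6 also held without the libraries numbered 4 (1.38 to 2.17). The covariate cannot show the share of the youngest embryos, since maternal levels did not simply follow it. Within edc-4, the maternal list averaged 5.775 log2 CPM in replicate 4 (score -1.568) and 5.776 in replicate 3 (score 0.433). A difference in that share stays open. Adult intestine carried into the libraries is argued against by its yolk transcripts. Vitellogenin genes summed to 2.01 ± 0.451 CPM with the allele and 1.86 ± 0.470 CPM without it (SD, n = 8 each), a ratio of 1.08. Between the same libraries chs-1, egg-1 and egg-2 differed 4.75-fold, 3.23-fold and 3.16-fold, and sperm genes also had a ratio of 1.08. The vitellogenin sums were low, and 1 of these 6 genes passed the filter. Vitellogenins are made in the intestine, so carried-over oocytes or gonad were not tested. A sequence variant linked to edc-3 acting on its neighbours cannot account for egg-1 and egg-2, since 2 of the 3 genes lie on another chromosome, but chs-1 lies 1.05 Mb from edc-3 and is not excluded by that. Loss of EDC-3 function may raise these oocyte transcripts. The near loss of the lmd-1 transcript occurred in the same libraries (0.442 CPM in edc-3 and 0.697 CPM in the double mutant, against 19.7 CPM in WT). An indirect effect of that linked change cannot be told apart from loss of EDC-3. Unlinked background shared by both strains with the allele was not tested, so an effect of EDC-3 loss remains a hypothesis found and tested on the same data.

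The shifts of whole gene lists followed the libraries numbered 4. Of 48 list calls over the 3 mutants, 8 held in the same direction without those 4 libraries, against 47, 45 and 43 without the libraries numbered 2, 3 and 5. A stage difference as tracked by muscle and cuticle genes stays open, since 36 of 48 calls held with that covariate but the list medians fell to 61.5% of their size, and other divisions of the libraries call as many lists. The muscle calls among the 48 are adjusted for their own list there and cannot count as a test. The ribosomal RNA share stays open too, since 46 of 47 calls held without ribosomal and mitochondrial RNA genes but that removal moved no median by more than 0.008 on the log2 scale and so tests nothing. A candidate explanation for most list shifts is thus the spread between harvests, with WT replicate 4 at one end of the range and edc-4 and double replicate 4 at the other (8 of 48 calls held).

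For the numbers of genes called between genotypes, chance division of the libraries is argued against. Of the 35 divisions of the 8 libraries in each comparison, 1 gave as many genes, the real one, in edc-3 against WT (24, highest other 0), edc-4 against WT (24, highest other 1), the double mutant against WT (35, highest other 0), the double mutant against edc-3 (6, highest other 0) and the double mutant against edc-4 (5, highest other 0). For the interaction, 3 of 100 drawn divisions gave 6 or more genes, the real one included, and the highest other gave 5475, which points to a structure of the libraries that this test does not identify. For lists, chance division of the libraries cannot be excluded as 23 of 35 divisions called at least the 13 lists of edc-3 (highest other 24), 19 of 35 at least the 16 of edc-4 (highest other 24) and 16 of 35 at least the 19 of the double mutant (highest other 23).

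Interaction terms passed the test for 6 genes, whose levels in these strains did not add on the log2 scale. They were log2 -7.365 for F59C6.15, -6.718 for F46C5.2, -5.468 for nas-25, -5.045 for F46C5.4, 1.09 for T25D10.4 and 1.586 for rer-1. All except F59C6.15 belong to the 14 clustered genes.

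Single libraries stood apart from the other 3 of their genotype in 9 of 148 groups of 4 examined, where chance gives about 1 in 20, or 7.4. Double replicate 4 had a first principal component score of 53.83 against -2.996 to 5.43 in the others. For egg-1, edc-4 replicate 3 was at 11.58 CPM (others 7.38 to 7.63). For T25D10.1, WT replicate 4 was at 9.371 CPM (others 6.75 to 7.18) and edc-4 replicate 2 at 4.332 CPM (others 3.02 to 3.13). Double replicate 5 had 5.187 CPM of pho-13 (others 3.76 to 3.90), and double replicate 4 had 17.78 CPM of ppw-2 (others 26.8 to 27.9). Y46G5A.6 was at 4.134 CPM in edc-4 replicate 2 (others 5.00 to 5.07), scrm-4 at 12.76 CPM in WT replicate 3 (others 4.67 to 6.02) and hmit-1.1 at 9.984 CPM in edc-3 replicate 5 (others 6.40 to 6.98).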

How the results depend on the processing

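The fit without the libraries numbered 4, the chromosome tests without the targeted genes, the overlaps with separate WT libraries and the allele effects over both backgrounds were chosen only after the data were seen, and the other alternatives before. For named genes, 726 values stayed on the same side of the threshold, 72 were weaker, 3 stronger and 0 reversed. With 1 library left out, 448 stayed and 112 were weaker. Values that stayed include those of edc-3 and edc-4 where they were not called. Of the named calls against WT, 7 of 17 in edc-3, 3 of 16 in edc-4 and 11 of 21 in the double mutant held in every setting. For list calls, 139 values stayed, 45 were weaker and 8 reversed, and with 1 library left out 313 stayed and 71 were weaker. Genes called in edc-3, edc-4 and the double mutant against WT went from 24, 24 and 35 to 39, 42 and 113 by DESeq2 and 45, 88 and 199 with the stage covariate, under which all 24, 24 and 35 remained. At an adjusted p under 0.01 they were 13 in edc-3 and 18 in the double mutant, without a low-count filter 40 and 65, and with only the groups compared 14 in edc-3 and 7 in edc-4. The double mutant against edc-3 went from 6 to 25 by DESeq2 and 40 with the stage covariate, and against edc-4 from 5 to 12 by DESeq2, 9 with the stage covariate, 12 without the filter and 2 at an adjusted p under 0.01. The interaction went from 6 to 17 by DESeq2, 15 with the stage covariate and 10 without the filter. Fewer groups give fewer residual degrees of freedom and a stricter threshold fewer calls by construction; otherwise the cause was not tested.

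Leaving out 1 library gave 14 to 24 genes in edc-3 (15 without edc-3 replicate 2, 14 without replicate 3), 15 to 24 in edc-4 (15 without edc-4 replicate 5), 17 to 29 in the double mutant (22 without WT replicate 4, 21 without WT replicate 5, 17 without double replicate 2), 4 to 5 in the double mutant against edc-3, 2 to 5 against edc-4 (3 without edc-4 replicate 2 or 5, 2 without double replicate 2, 3 or 5) and 5 to 7 for the interaction. Lists called ranged from 5 to 20 in edc-3 (5 without WT replicate 4, 6 without edc-3 replicate 4, 20 without edc-3 replicate 5), 4 to 20 in edc-4 (4 without WT replicate 4) and 13 to 21 in the double mutant. The log2 difference of the edc-3 transcript in edc-3 ranged from -0.533 to -0.378, and it no longer passed, at -0.499 to -0.408 with exact p = 0.0571, when an edc-3 library was left out.

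With an estimated correlation 0, 0 and 0 lists were called in the 3 mutants, and by fry's directional test 0, 0 and 0. Without the libraries numbered 4 the double mutant had 10 lists. Medians then called in the opposite direction were, in edc-3, germ granule -0.097, proteasome -0.064 and cell cycle -0.071; in edc-4, germ granule -0.085, small RNA -0.080, cell cycle -0.054 and ribosomal proteins 0.137; and, in the double mutant, histones -0.099. The correlation of edc-3 and edc-4 fold changes (0.561) was -0.1397, 0.2023, 0.1655, 0.2235, 0.0729 and 0.0407 over the 6 divisions of the WT libraries, which remove the shared control. At an adjusted p under 0.01, 5 chromosome tests passed, and with edc-3 and edc-4 left out of the genes counted 3 did instead of 8, all on chromosome II.

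The labels give no pairing beyond the replicate number, and deviations of same-numbered libraries did not all correlate above 0.1. They did in 2 of 12 pairs of a mutant and WT (-0.493 to 0.211) and in 6 of 8 pairs of the double and a single mutant (-0.054 to 0.656), so a link among the mutants is not excluded, and 7 of 16 libraries matched best with their own number. With a replicate block, 26, 25, 36, 4, 5 and 7 genes were called in the 6 comparisons, of which 24, 23, 30, 4, 5 and 6 were among the original calls, along with 14, 15 and 20 lists. The correlation of edc-3 and edc-4 fold changes was 0.561 with the block too. Every genotype holds every number, so a block cannot change that value and it tests nothing. Simulated changes of 1.5-fold were recovered in 20.4% of genes for the double mutant against WT, so this number of libraries limits what small changes can be seen.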

Other observations

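The effect of each allele averaged over both backgrounds, 8 libraries with the allele against 8 without it, was tested only after the other results were seen. No gene list was tested for this averaged effect, and the genes below were named after their values were seen. The maternal list tested above holds rme-2 but not perm-1, plk-3 or gfat-2. Without the libraries numbered 4 its call was lost in edc-3 and held in the double mutant. The yolk receptor gene rme-2 rose 3.06-fold with the edc-3 allele, from 16.38 ± 7.45 to 50.1 ± 16.6 CPM (SD, n = 8 each, adjusted p = 0.0189 by the edgeR quasi-likelihood test). The eggshell gene perm-1 rose 2.32-fold (adjusted p = 0.0207), the polo-like kinase gene plk-3 2.34-fold (adjusted p = 0.0189) and gfat-2, for an enzyme that makes the sugar precursor of chitin, 1.98-fold (adjusted p = 0.0412). The Argonaute gene ppw-2 rose 1.77-fold (adjusted p = 0.00211) and the kinase gene rskn-1 1.67-fold (adjusted p = 0.00902), and scrm-4 fell by 1.25 on the log2 scale (adjusted p = 0.00463). The rskn-1 gene (chromosome I, 8573852 to 8580205) lies close to edc-3 (chromosome I, 8602125 to 8605162). For rskn-1, an effect of sequence linked to the allele can therefore not be told apart from loss of EDC-3. In total 25 genes were called, 20 higher and 5 lower, 8 of them in none of the comparisons above, and 728 had an unadjusted p under 0.05. Of the 25, 6 lie in or near the 3 clusters of genes that separate WT from all mutants, and F59C6.15 and C55C3.3 are called although the double mutant was near WT, so the average does not describe both backgrounds for them. The count was 94 with the stage covariate, including all 25, and 25 without the libraries numbered 4, of which 21 were shared. There perm-1 (log2 1.146 against 1.216 with all libraries, adjusted p = 0.103) and gfat-2 (log2 1.01 against 0.98, adjusted p = 0.0765) no longer passed in fewer libraries although their differences stayed about as large, while rme-2 (adjusted p = 0.0195) and plk-3 (0.0214) did. Of 100 drawn regroupings within each background, 2 gave 25 or more genes, the real one included. The highest other gave 3238, which points to a structure of the libraries. Such a count does not bear on any single gene among the 25.

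With the edc-4 allele, 33 genes were called, 19 higher and 14 lower, 7 of them in none of the comparisons above, and 1802 had an unadjusted p under 0.05, with 8 of the 33 in or near the clusters and edc-4 itself among them. F59C6.15 and C55C3.3 are among the lower genes because of their level in the edc-3 strain alone, and F59C6.15 was higher in edc-4 than in WT (17.2 against 6.77 CPM). The ephrin gene efn-4 rose from 71.0 ± 7.18 to 98.2 ± 4.41 CPM (adjusted p = 0.00388), T26C12.3 from 45.9 ± 3.21 to 67.5 ± 6.64 CPM (adjusted p = 0.00118) and F58D5.5 from 104.1 ± 21.8 to 183 ± 42.9 CPM (SD, n = 8 each, adjusted p = 0.00584). The transporter gene hmit-1.1 fell by 1.09 on the log2 scale (adjusted p = 0.0194), and by 0.92 without the libraries numbered 4, where it no longer passed in fewer libraries (adjusted p = 0.0994). The count was 238 with the stage covariate, including all 33, and 22 without the libraries numbered 4, of which 17 were shared. Of 100 drawn regroupings, 2 gave 33 or more genes, the real one included, and the highest other gave 4881.

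The small nucleolar RNA F59C6.15, C55C3.3 and the pseudogene Y51A2D.23 were high in the edc-3 strain and near WT in the double mutant, which carries the same allele. F59C6.15 was at 422 ± 21.9 CPM in edc-3 and 6.46 ± 0.811 CPM in the double mutant, C55C3.3 at 2.21 ± 0.331 and 0.207 ± 0.0605 CPM, and Y51A2D.23 at 1.27 ± 0.415 and 0.108 ± 0.0939 CPM (SD, n = 4 each). Whether the edc-4 allele or a difference between the strains sets these levels was not tested, since each genotype is a single strain.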
